A study of Mus musculus with 4 samples.

How the data were processed

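Lens RNA of 2 MafG-/-:MafK+/- and 2 MafG+/-:MafK+/- samples was measured, each on 1 Illumina MouseWG-6 array. Per the labels' protocols, total RNA was isolated with an RNeasy mini kit and labelled with biotin. The deposited scanner table gives bead intensity per probe, on a linear scale, made with Illumina software at version 1.9.0 and without normalization between arrays, per the file headers. The deposited detection p-values give, per array and probe, the share of negative controls at or above its signal. The table also holds the deposited standard error of each signal over its beads and the number of beads, and a second block with 974 control probes, 936 of them negative controls. Its probe coordinates name no genome build. The probe intensities were already background-subtracted, while the control block was not. This was found from the values: the detection p-values were recovered to within 0.015 when each array's mean negative control (43.7, 43.1, 42.8 and 40.1 for mutants 1 and 2 and controls 1 and 2) was added back, and not otherwise. Each array's mean was therefore added back before any step. A second table holds the authors' processed values, on a linear intensity scale. On each array they lie on a straight line of the deposited signal, with slopes of 3.93, 5.15, 3.25 and 6.26, intercepts of 47.9, 36.0, 57.3 and 64.4 and medians of 53.4, 42.5, 62.1 and 71.3. Their scale is thus known, they hold no centring of genes and 1 value per sample, and what set the slopes is not given in the sources used here. They were used only as an alternative, floored at 16 before log2.

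The detected probes numbered 11721 and 11739 on the mutant arrays and 13117 and 11266 on the control arrays, of 45281. Log2 intensities of replicates correlated across genes at 0.995 (mutants) and 0.990 (controls), against 0.986 to 0.990 between groups. The controls were no closer to each other (median difference 0.15) than control 1 was to mutant 1 (0.13), and they lay apart on the second principal component (-12.6 and 7.74), which held 28.9% of the variance. Differences of more than 2 bead standard errors were counted among probes with detection p under 0.01 on both arrays, after scaling by the median ratio. They were seen in 15.1% of these probes between the mutant arrays and 37.3% between the control arrays, against 32.3% to 37.6% between groups. Probes were named through the Entrez identifier (29586 probes) or accession (2759) in a mouse RefSeq gene table, and 12936 kept the symbol of the file. That table (assembly GRCm38.p6) was used only for names and for which genes neighbour each other.

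Background correction and normalization used neqc of limma 3.58.1 in R 4.3.3, with the negative controls and an offset of 16, followed by quantile normalization. Because of the offset, changes of dim probes are understated. Probes with detection p under 0.05 on both arrays of at least 1 group were kept (11549 probes), and each gene was represented by its kept probe with the highest mean, giving 8929 genes. Groups were compared with lmFit and eBayes, with no covariate and 2 residual degrees of freedom (6.52 prior degrees of freedom), and Benjamini-Hochberg adjusted p under 0.05 called a gene changed. For a gene not above background in 1 group, the fold is a lower bound: the mean of the brighter group over the mean, in the dimmer group, of the higher of the probe's own value and the lowest value of a detected probe on that array. Where different probes of a changed gene were kept (34 genes), 30 had the same direction on average. The 4 that did not were Dctn4, Itgb1bp1, Riok1 and Rps3.

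The 29 gene lists and the alternatives were fixed before the data were examined, and 27 lists with at least 3 measured genes were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives. Of 673 list entries, 648 matched a gene of the file. The old name Sip1 and Rpl10 were left out because their probes belong to other genes. For the lists of small Maf and partner factors, lens fibre, ribosomal, erythrocyte and macrophage genes, the median, the mean and the test differed in sign, and none of these was called. Named genes were Mafg and Mafk, the 10 largest rises and 10 largest falls among changed genes without gene-model names and with non-overlapping arrays, up to 4 list members with the smallest p (fewer are named here) and the changed members of the lists, a panel of 5 genes from the study's own report, and the sex-linked genes. A result for 1 changed list member is not reported here. Changed genes near Mafg were tested with Fisher's exact test, two-sided, over 7688 genes with a known position.

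Alternatives were no background correction, median centring, the authors' values, 2 other filters on dim probes, 2 other ways to treat several probes, a trended and robust variance, leaving out each array, a replicate block, 2 other thresholds, the 2 other set tests and 2 other windows. Added after seeing the data were a background from the detection p-values, tests of neighbouring changed genes, of the share of changed genes near Mafg, of cornea markers and of the shrinkage of changed genes, a bootstrap interval for other probes and a Fisher test of the ontology terms in the file. The steps were tested on simulated arrays of this comparison with 11415 genes tested. In these, 200 genes were changed and the genes of the sterol list were shifted besides. With 50 genes at each size, 4.0% were recovered at 1.5-fold, 40.0% at 2-fold, 70.0% at 3-fold and 80.0% at 4-fold, none in the wrong direction. Of 103 called genes, 5 were unchanged ones, with the shifted list genes counted as changed. With no gene changed, 0 were called. The simulated noise was alike in both groups, while the residual SD of the data was 0.12 in mutants and 0.17 in controls. These rates may therefore not hold for the 8929 genes tested here. The simulated sizes came out smaller than made, with a median log2 change of 1.41 for 4-fold changes.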

Results

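MafG and MafK are small Maf proteins, bZIP transcription factors without an activation domain of their own that bind DNA as partners of other bZIP proteins. The series compared lenses of mice lacking both copies of Mafg and 1 copy of Mafk, which the labels describe as having cataract, with lenses of mice carrying 1 copy of each gene, described as free of cataract. Genotype and cataract thus cannot be told apart in these samples. All mice were 2 months old and of a mixed background of 129Sv/J, C57BL/6J and ICR. Total RNA from 2 mutant and 2 control lens samples was hybridised to 4 Illumina MouseWG-6 bead arrays, 1 per sample, with 45281 probes each. Signal stood above background (detection p under 0.05) for 25.9% of the probes on each mutant array, and for 29.0% and 24.9% on control arrays 1 and 2. Nothing in the labels says whether a sample was 1 animal or a pool, so p-values measure the spread between these samples only, and their number limits the precision. Values below are normalized log2 intensities, as mean ± SD with n = 2 arrays per group, and changes are mutant minus control with their standard error.

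The targeted gene was measured first. The Mafg probe (chromosome 11, 120489696 to 120489745, in a build that the file does not name, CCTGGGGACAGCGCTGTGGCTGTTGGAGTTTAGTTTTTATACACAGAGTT) gave background-subtracted signals of -0.1 and 4.9 on the mutant arrays, neither above background, and 138.4 and 66.9 on the control arrays. Mafg was at least 4.82-fold lower in the mutants (4.35 ± 0.13 against 6.83 ± 0.09, adjusted p = 3.94e-05). Whether this probe lies inside the deleted part of the gene is not given in the sources used here. The only Mafk probe (chromosome 5, 140278292 to 140278341, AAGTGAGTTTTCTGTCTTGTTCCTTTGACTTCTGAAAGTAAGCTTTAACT) had signals from -2.1 to 1.1 and was not above background on any array, so Mafk has no fold change. Neither of the 2 probes for Maff, the remaining small Maf gene, was above background on any array. Among the partner factors, Bach2, a repressor that pairs with small Maf proteins, differed by 0.52 ± 0.14 (adjusted p = 0.16) and Nfe2l1 by 0.14 ± 0.12 (adjusted p = 0.717). No probe for Nfe2l2, which encodes NRF2, Bach1, Nfe2 or Nfe2l3 was above background on any array, so these partners were not measured. Of the 4 measured genes on the list of small Maf and partner factors, Mafg alone passed over all genes, and 1 higher (Bach2) and 1 lower passed when adjusted over the list alone (camera for the list, adjusted p = 0.699). The list's other 3 measured members lay above 0, with Keap1 at 0.02. A fall of this list thus cannot be told from the loss of Mafg itself.

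In mutant lenses, several genes of sterol synthesis and of the stress response of the endoplasmic reticulum were higher, as was Hmox1, and Aldh3a1, an aldehyde dehydrogenase abundant in cornea and lens, was lower. As sets, the sterol and stress-response lists passed camera at a preset correlation between genes. Neither passed with an estimated correlation, a test on 2 degrees of freedom (adjusted p = 0.336 and 0.719). The alternative test fry called both higher (adjusted p = 0.00446 and 0.0447). Of 8929 tested genes, 142 changed (limma, adjusted p under 0.05), of which 73 were higher and 69 lower in the mutants. Among named genes, the largest rises were in Dctn4, a dynactin subunit not above background in the controls (at least 4.30-fold higher, while its other kept probe differed by -0.13), Hmgxb3 (3.36-fold) and Ddit3, which encodes the stress-induced factor CHOP (3.30-fold). They were followed by Fdps (2.74-fold), Cyp51 (2.69-fold), BC020108 (2.60-fold), Msmo1 (2.52-fold), Sqle (2.48-fold), Klhl9 (2.48-fold) and Hmox1 (2.47-fold). Hmox1, heme oxygenase 1, went from 9.79 ± 0.20 to 11.09 ± 0.01 (adjusted p = 0.00158, probe on chromosome 8, 77619162 to 77619211). The deepest falls besides Mafg were in Ttc27 (7.78-fold lower, above background on 1 mutant array), Igk-C, the constant region of the immunoglobulin kappa chain (4.09-fold lower, above background on 1 mutant array), and Aldh3a1. Aldh3a1 was 3.53-fold lower, at 9.11 ± 0.14 against 10.93 ± 0.13 (adjusted p = 0.000266, probe on chromosome 11, 61031743 to 61031792). Next came Alox5ap, which activates 5-lipoxygenase (2.53-fold lower), Bgn, the matrix proteoglycan biglycan (at least 2.16-fold lower and not above background in the mutants), Pbld1 (2.37-fold), Lims2 (2.37-fold), R3hdml (2.34-fold) and the exonuclease gene Trex1 (2.15-fold).

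**Figure D1:**
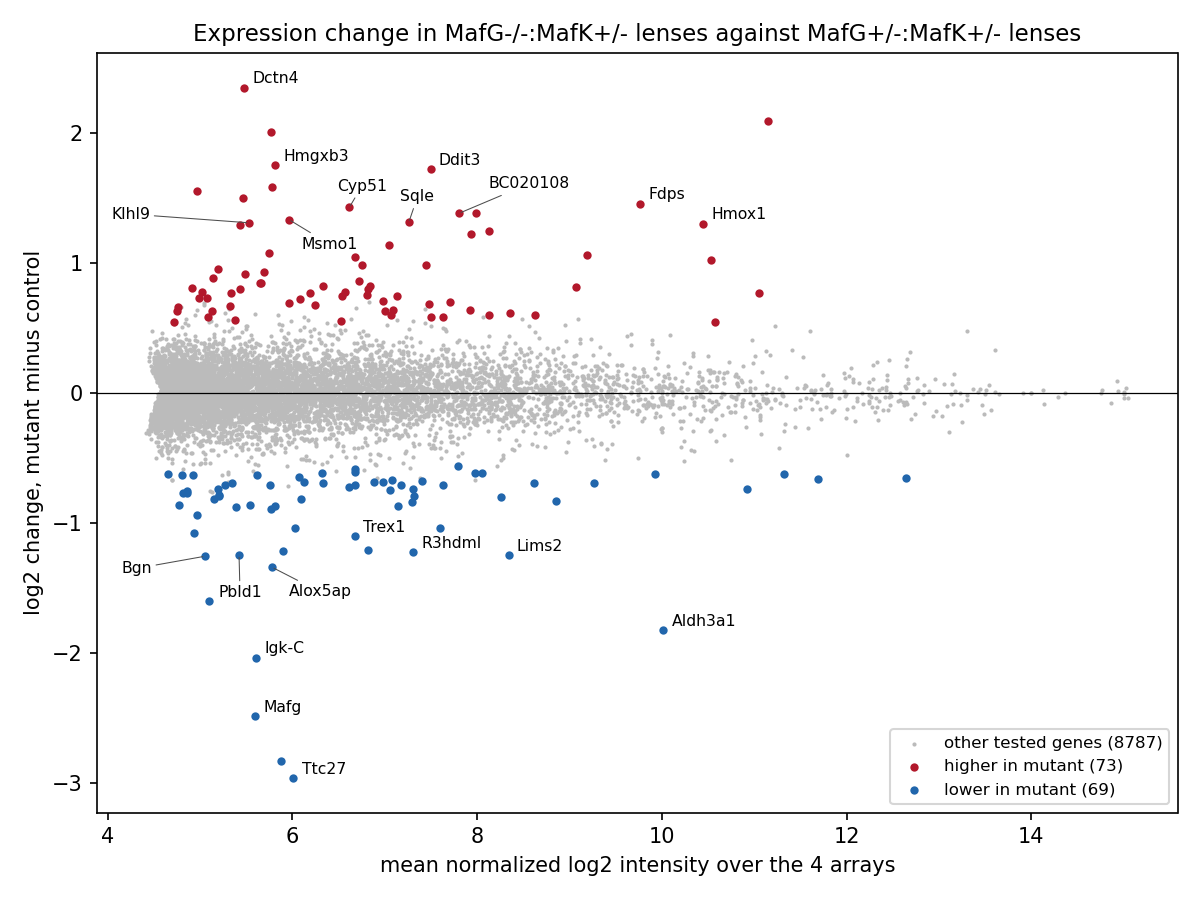
Change in expression (mutant minus control, log2) against the mean normalized log2 intensity over the 4 arrays for the 8929 tested genes. The 73 genes higher in mutants are red, the 69 lower are blue, and the named genes with the largest changes are labelled, from Ttc27 at the bottom to Dctn4 at the top.

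In all 142 genes both mutant arrays lay on one side of both control arrays. The call itself selects for this, so it is no added support. Of all tested genes, 42.2% had such arrays, where chance gives 33.3%. A change of at least 2-fold was seen in 24 of the higher and 17 of the lower genes. At an unadjusted p under 0.05, 1059 genes passed, where 446 are expected by chance. Of the 142, 24 carry only a gene-model name. The count rests on all 4 arrays: without mutant 1, mutant 2, control 1 or control 2, 45, 32, 42 and 28 genes passed. Among 41 changed genes followed through the alternatives, the calls of Creld2, Calr, Sdf2l1, Dnajb9, Hsp90b1, Hspb1, Hsd17b7, Insig1, Mgst1, Gsto1, Txnip, Crygf, Mt1, Tmsb10, Ccng1, Rps3, Car14 and Pdgfrb ended whichever single array was left out. Those of R3hdml, Pbld1 and Stard4 ended in 3 of these 4 cases, those of Trex1 and Xbp1 in 2 and that of Sqle in 1. The split between higher and lower was not the same on the authors' processed values, where 59 were higher and 540 lower and the median of all genes stood at -0.16.

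Several genes of sterol synthesis were higher in the mutants. Of 19 measured members of this list, 8 rose and none fell over all genes tested, and 13 rose adjusted over the list alone. Fdps, which makes farnesyl diphosphate, rose from 9.03 ± 0.07 to 10.49 ± 0.01 (adjusted p = 0.000446). Sqle, the squalene epoxidase, rose by 1.31 ± 0.12, and the demethylation enzymes Cyp51 and Msmo1 by 1.43 ± 0.12 and 1.33 ± 0.13. Stard4, a sterol carrier, rose by 0.93 ± 0.13, Hsd17b7 by 0.86 ± 0.12 and Insig1, a sterol sensor, by 0.69 ± 0.12. The list's median change was 0.42 (camera with a preset correlation of 0.01, adjusted p = 8.83e-15 over 27 lists). With an estimated correlation, the adjusted p was 0.336.

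Some genes of the unfolded protein and integrated stress response were also higher. Of 22 measured members, 5 rose and none fell over all genes tested, and 11 rose and 1 fell adjusted over the list alone. Ddit3 rose from 6.63 ± 0.15 to 8.36 ± 0.02 (adjusted p = 0.000266) and Xbp1, a factor of the unfolded protein response, from 8.66 ± 0.06 to 9.71 ± 0.01 (adjusted p = 0.00204). Creld2 rose by 0.82 ± 0.11 and the chaperone gene Calr by 0.68 ± 0.12, while Sdf2l1, not above background in the controls, was at least 1.37-fold higher, a call kept in 4 of 13 alternatives. The median change was 0.41 (camera, adjusted p = 1.13e-07). With an estimated correlation, the adjusted p was 0.719. In the list of heat shock proteins and chaperones, 2 of 20 rose and 1 fell, and 3 rose and 1 fell adjusted over the list alone. The 2 that rose, Dnajb9 (0.78 ± 0.13) and Hsp90b1 (0.62 ± 0.11), encode chaperones of the endoplasmic reticulum, and the one that fell, Hspb1, encodes a small heat shock protein. As a set the heat shock list did not pass (camera, adjusted p = 0.227), although on the authors' processed values it did (adjusted p = 0.0146).

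**Figure D2:**
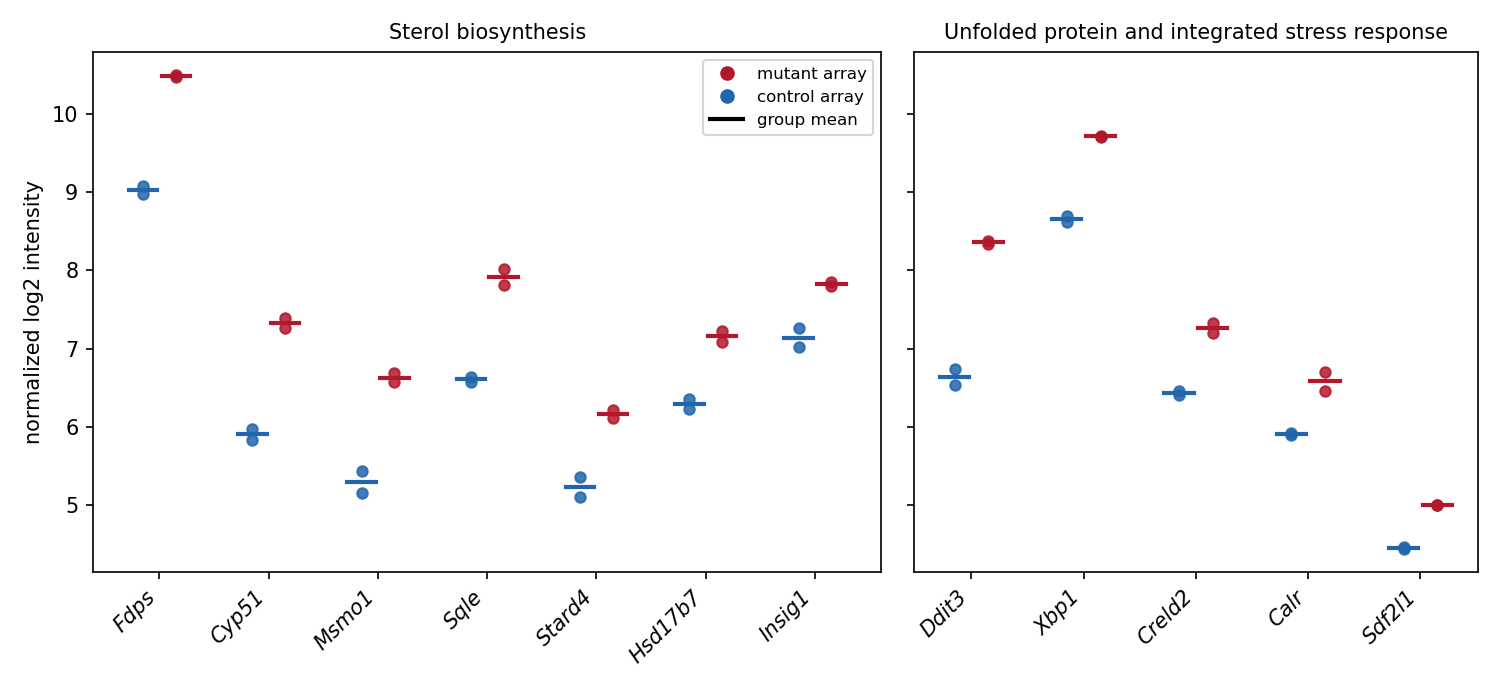
Normalized log2 intensity of 7 sterol synthesis genes and 5 stress-response genes that changed, with 1 point per array and a bar at each group's mean. For each gene both mutant arrays (red) lie above both control arrays (blue), with Fdps the brightest and Sdf2l1 close to background in the controls.

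The antioxidant genes did not move one way. Of 23 measured targets of NRF2 and the antioxidant response element, the DNA motif that small Maf proteins bind with NRF2, 1 rose (Hmox1) and 1 fell (Mgst1, a microsomal glutathione transferase, by 0.56 ± 0.11). Adjusted over the list alone, 6 rose and 1 fell. Ephx1 and Sqstm1 differed by 0.49 ± 0.11 (adjusted p = 0.0805) and 0.47 ± 0.11 (adjusted p = 0.0924). The list's median change was 0.13, and camera placed it higher (adjusted p = 0.00288). With an estimated correlation, the adjusted p was 0.719. Of 21 glutathione and redox enzymes, 2 fell, also adjusted over the list alone: Gsto1, a glutathione transferase (0.67 ± 0.12 lower), and Txnip, which inhibits thioredoxin (0.69 ± 0.13 lower). Prdx3 and Gstz1 differed by -0.29 ± 0.12 and -0.26 ± 0.11 (adjusted p = 0.389 and 0.412). The list's median change was -0.15 (camera, adjusted p = 0.0389). With an estimated correlation, the adjusted p was 0.76. Without mutant 1 both calls ended (adjusted p = 0.0535 each), and without control 2 that of the redox list did (adjusted p = 0.812).

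Crystallins, the main lens proteins, showed 1 change among 16 measured genes, over all genes and adjusted over the list alone. Crygf fell by 0.68 ± 0.11 (adjusted p = 0.0258, probe on chromosome 1, 65974809 to 65974858). Crygn and Cryge differed by -0.31 ± 0.12 and -0.27 ± 0.12 (adjusted p = 0.349 and 0.43), and the list's median change was -0.02 (camera, adjusted p = 0.25). No gene of the 20 for lens fibre structure and membrane passed, by either adjustment. Their smallest p-values were those of Lgsn, lengsin, at -0.48 ± 0.13 (adjusted p = 0.148), and Dnase2b, the nuclease that clears fibre DNA, at -0.39 ± 0.11 (adjusted p = 0.18). None of 13 lens transcription factors passed by either adjustment, with Meis1 at -0.30 ± 0.18 and Maf at 0.15 ± 0.11 (adjusted p = 0.559 and 0.637). Of 12 lens epithelium genes, 1 fell, the metallothionein Mt1 (0.89 ± 0.11 lower), and 2 rose and 2 fell adjusted over the list alone. Pdgfra and Aqp1 differed by 0.45 ± 0.12 and 0.41 ± 0.11 (adjusted p = 0.141 and 0.161). The camera adjusted p was 0.767 for the fibre list, 0.699 for the factors and 0.699 for the epithelium.

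Of 39 measured genes on the list of human cataract orthologues, 3 fell and none rose. They were Aldh3a1, Crygf and Hspb1 (0.66 ± 0.13 lower, adjusted p = 0.0482), and with Pcbd1 4 fell adjusted over the list alone. Pcbd1, which encodes a pterin dehydratase, differed by -0.65 ± 0.15 (adjusted p = 0.0923). No other gene of the list passed by either adjustment. Whether Aldh3a1, Crygf, Hspb1 and Pcbd1 are themselves linked to cataract in humans was not checked here. These 4 and Hmox1 are genes recalled from the study's own report, which chose them on these samples, so neither their direction here nor the counts and tests of this list are independent evidence. The list as a whole did not pass (median change -0.03, camera, adjusted p = 0.249), while the alternative test fry of limma called it lower (adjusted p = 0.0447).

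In other gene groups single members changed. Bgn alone fell among 18 measured matrix genes, also adjusted over the list alone, and Ccng1, cyclin G1, among 14 p53 targets (0.69 ± 0.13 lower), with 2 higher and 2 lower p53 targets adjusted over the list alone. Tmsb10, thymosin beta 10, rose among 18 cytoskeletal genes (0.55 ± 0.11), with 1 higher and 1 lower adjusted over the list alone. Rps3 rose among 20 ribosomal protein genes (0.77 ± 0.12), also adjusted over the list alone, although its other probe differed by -0.27. No member passed over all genes in 4 lists by limma with an adjusted p: 22 genes of oxidative phosphorylation (Ndufa4 at -0.42 ± 0.12, adjusted p = 0.186), 19 of glycolysis (Slc2a1 at 0.44 ± 0.13, adjusted p = 0.222), 11 of the cell cycle (Mcm2 at 0.30 ± 0.13, adjusted p = 0.384) and 12 of the interferon response (H2-D1 at 0.60 ± 0.14, adjusted p = 0.105). Among 10 immediate early genes none passed either, with Egr1, not above background in the controls, at 0.59 or more (adjusted p = 0.0884). Adjusted over the list alone, 2 immediate early genes and 1 interferon gene were higher, and none of the other 3 lists had any. The camera adjusted p of these 9 lists lay between 0.227 and 0.778.

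Markers of neighbouring tissues were mostly near background. No measured marker passed for photoreceptors (7 measured, median -0.18, with Gnb1 at 0.27 ± 0.11 the only one above 0), pigment epithelium (4 measured, Oca2 at -0.12 ± 0.11), macrophages (3 measured, Aif1 at -0.13 ± 0.14), erythrocytes (3 measured, median 0.15, with Slc4a1 at -0.39 ± 0.13 the only one below 0) or neurons (6 measured, Uchl1 at -0.50 ± 0.12). Adjusted over the list alone, 1 erythrocyte and 1 neuronal marker were lower, and no marker of the other 3 tissues passed. Among 8 markers of ciliary body and iris muscle, Car14, a carbonic anhydrase, rose by 0.58 ± 0.11, although its other kept probe differed by 0.04, with 1 higher and 1 lower adjusted over the list alone. Of the 3 measured cornea markers, Aldh3a1 alone fell, also adjusted over the list alone, and none of Krt12, Krt5, Krt14, Kera and Lum was above background on any array. Tkt and Krt4 differed by 0.20 ± 0.11 and -0.04 ± 0.18, so a fall of this list would rest on Aldh3a1. Pdgfrb, a pericyte marker, rose by 0.63 ± 0.11, above background on 1 control array and kept in 5 of 13 alternatives, as 1 of 2 measured endothelial and pericyte genes, also adjusted over the list alone. The camera adjusted p of the tested marker lists lay between 0.227 and 0.988. Xist was above background on all 4 arrays (0.10 ± 0.19, adjusted p = 0.88) and no probe for the Y-linked Ddx3y, Eif2s3y, Kdm5d or Uty was on any.

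**Figure D3:**
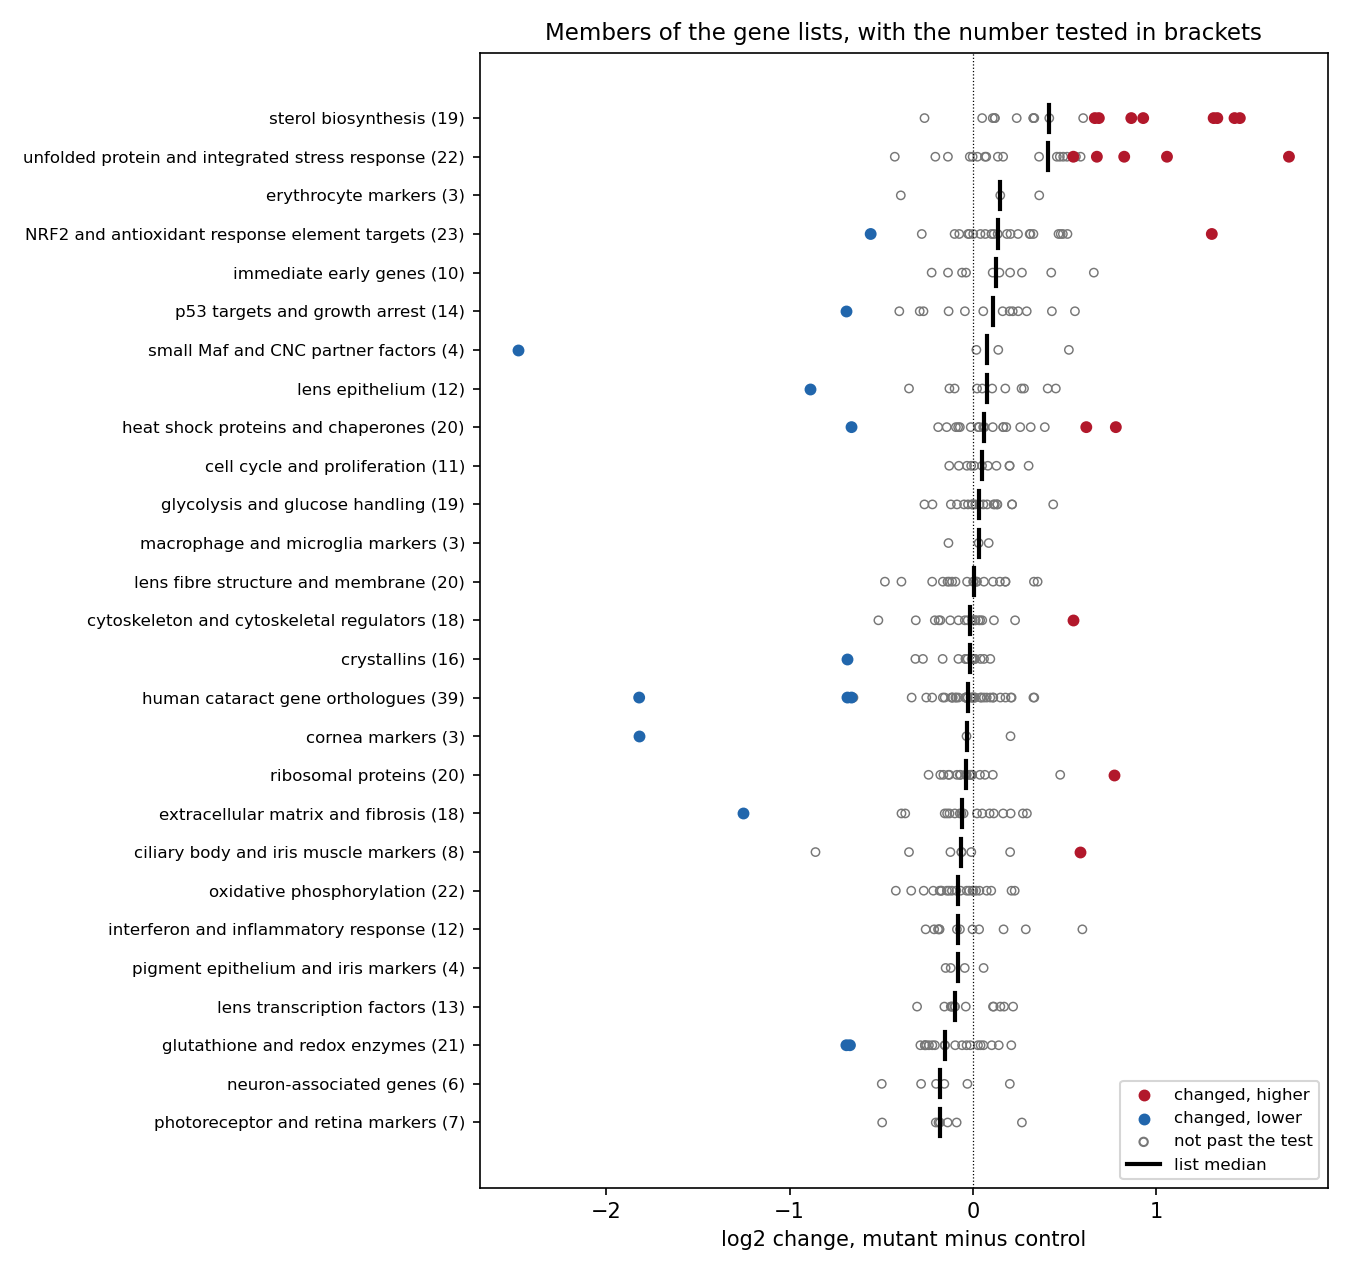
Change in expression (mutant minus control, log2) of each measured member of the 27 lists with at least 3 measured genes, ordered by list median (black bar). Filled points passed the test over all genes (red higher, blue lower) and open points did not, and the sterol and stress-response lists have the highest medians, at 0.42 and 0.41.

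Mutants carry 2 copies and controls 1 copy of the targeted chromosome 11, so genes beside Mafg could differ by strain of origin, and these were tested apart. Within 10 Mb of Mafg, 3 of 103 tested genes changed (2.91%), against 118 of 7585 elsewhere (1.56%). The odds ratio was 1.90 (95% confidence interval 0.38 to 5.85, Fisher's exact test, two-sided, p = 0.221), which does not exclude an excess close to the gene. The 3 genes were Fn3krp (1.29 ± 0.15 higher), its neighbour Fn3k, a fructosamine kinase gene (0.84 ± 0.12 lower), and Gaa, the acid glucosidase gene (0.73 ± 0.14 higher), at 0.80, 0.81 and 1.36 Mb from Mafg. With windows of 5 and 20 Mb the odds ratio was 2.47 and 1.11 (Fisher's exact test, two-sided, p = 0.131 and 0.753).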

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

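The background from the detection p-values was the only alternative here chosen after seeing the data, and it gave 141 genes. The count of 142 changed genes stayed within 1.5 times with the stricter filter (129), every probe (134), the mean of probes (141) and unadjusted p with 1.5-fold (162). It was 271 without background correction (134 shared), 43 with median centring (all shared), 599 on the authors' values (124 shared; 59 higher and 540 lower, with the median of all genes at -0.16), 293 with trend and robust variance and 220 at adjusted p under 0.1. With no filter 30561 genes were tested and 32 called. With 1 array left out it ranged from 28 to 45 (45, 32, 42 and 28 without mutant 1, mutant 2, control 1 and control 2); the lone array is then assumed to vary like the other group, and fewer samples enter. The cause of the other shifts was not tested. Mafg stayed lower and past the threshold in every alternative that measured it, from -3.20 to -1.35; the stricter filter gave no value.

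The replicate numbers do not pair the samples by any label, and deviations of same-numbered samples correlated at 0.02. With the replicate block 304 genes were called (147 higher, 157 lower) and 6 lists. The arrays of all 142 changed genes did not overlap, so leaving out 1 array could hardly reverse a gene. With every probe tested, a gene was followed by its main probe, so the opposing probes of Dctn4 and Rps3 did not count there. Of 41 changed genes followed through the alternatives, none changed direction in any alternative, which was largely fixed in advance in these settings. Between 16 and 20 stayed past the threshold with 1 array left out, 21 with centring and 14 with no filter. Ddit3, Fdps, Cyp51, Aldh3a1, Dctn4 and Ttc27 stayed past it wherever measured.

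The 4 called lists became 0 with an estimated correlation, a test on 2 degrees of freedom, 6 with fry (sterol, stress response, p53, and lower for cataract, neuron and cornea), and 2 to 6 with 1 array left out (2 without mutant 1). The sterol and stress-response lists stayed past the threshold in all other alternatives. The NRF2 list was lost with every probe (adjusted p = 0.0619) and the redox list on the authors' values (adjusted p = 0.267). Of lists not called, the test of the erythrocyte list turned upward on the authors' values (median 0.00604), with no filter (0.0970), with the block (0.149) and without mutant 1 (0.717), against -0.423 without mutant 2. The test of the small Maf list turned upward with the stricter filter (median 0.138), every probe (0.0724) and without control 1 (0.117), in a range of 0.0314 to 0.126 with 1 array left out, and that of the cornea list with no filter (0.0207). Both lists passed as lower on the authors' values (adjusted p = 0.00217 and 0.0116) and with the block (0.000369 and 0.000144). Mafg and Aldh3a1 were their only genes among the 142. The heat shock list passed on the authors' values (0.0146), the photoreceptor list with no filter (0.00386) and without control 2 (0.0417), and the immediate early and erythrocyte lists without mutant 2 (0.00766 each). The odds ratio near Mafg passed in no alternative. It was 0.611 without background correction, 0 with no filter, 0.612 with the stricter filter, 0.877 with trend and robust variance, and 0 to 5.70 with 1 array left out (0 without mutant 2 and without control 2, 5.70 without control 1). Small differences turned for Xist (-0.0492 on the authors' values, -0.0679 without control 2, and -0.179 to 0.391 with 1 array left out) and Aif1 (-0.301 to 0.0613 with 1 array left out). The cause was not tested.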

Other observations

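The tests of the share of changed genes that lie near Mafg (unlike the odds ratio there, which was planned), of neighbouring changed genes, of cornea markers, of the ontology terms and of the shrinkage of changed genes, and the bootstrap interval for other probes, were chosen only after the results were seen, as were the genes named in this paragraph and the next. Some changed genes outside the lists are given singly, and no test was made of them as groups. They were not followed through the alternatives, where the calls of followed genes with an adjusted p near the threshold often ended. Creb3, a membrane-bound factor of the endoplasmic reticulum, was 1.47-fold higher (adjusted p = 0.0468), Serp1 was higher by 0.58 on the log2 scale (adjusted p = 0.0385), Sel1l, of the degradation machinery, was 1.48-fold higher (adjusted p = 0.0482) and Kdelr2, the retrieval receptor, 1.65-fold (adjusted p = 0.0155). Aacs was 1.68-fold and Acat2 1.71-fold higher, while Dgat2, a triglyceride synthesis enzyme, was at least 1.83-fold lower and not above background in the mutants. Cyp26a1, which breaks down retinoic acid, was 2.11-fold higher (adjusted p = 0.00463, with its other kept probe at 0.25) and Aldh1a3, which makes it, 1.81-fold lower (adjusted p = 0.0397). Tmem114, linked to cataract in humans, was 1.69-fold higher (adjusted p = 0.0258).

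In the file's own ontology annotation, 2 of 2000 tests passed after adjustment, both for genes higher in mutants. They were the formation of steroids (5 of 29 tested genes) and of cholesterol (4 of 15), each at adjusted p = 0.00537 by Fisher's exact test. Formation of sterols (3 of 17, adjusted p = 0.190), formation of lipids (adjusted p = 0.321), protein folding (adjusted p = 0.370), binding of unfolded proteins (adjusted p = 0.732) and lipid metabolism (adjusted p = 0.871) did not pass for the higher genes by the same exact test. On chromosome 18, 4 changed genes that were all higher (Dctn4, Arsi, Pdgfrb and Hmgxb3) lay within 0.61 Mb, among 10 tested genes there. Of the other tested genes there, none passed. Synpo (0.64), Rps14 (0.48), Ndst1 (0.19) and Csf1r (0.09) lay above 0, and Camk2a (-0.28) and Tcof1 (-0.11) below. In 1000 random draws of as many tested genes, 75 held a 1 Mb window with 4. The draws ignored direction and genes short of the threshold, so they cannot settle whether this stretch arose by chance. The second kept probe of Dctn4 differed by -0.13.

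The 142 changed genes on a mixed background were weighed against strain differences. The tables argue against a segment around Mafg as their main source, since 2.48% of those with a known position (3 of 121) lay within 10 Mb of it, although for those 3, all within 1.36 Mb, it stays open. Other segments stay open: 21 changed genes had the next one within 2 Mb, where random draws gave 14 to 26 (5th to 95th percentile, permutation p = 0.425, one-sided), but many segments with 1 changed gene each would give such a count too, so the bound written for this test could not exclude them. Sequence differences under single probes stay open as well. In 34 genes with another kept probe, that probe moved by 0.523 of the change (95% bootstrap interval 0.266 to 0.825). This lies above the bound of 0.5 set beforehand by less than its spread. The other probes were the dimmer ones, whose changes the offset shrinks more, and the changed probes were picked by their call. A ratio under 1 would thus be seen without sequence differences too, so their part in the changes cannot be told from it. With 3 splits of the 4 arrays into pairs, 1 of which gave 142 genes and the highest other 0, no share under 0.05 can be reached, and the genotype itself was not tested apart from these.

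The rise of the sterol and stress-response lists was weighed against scaling and single arrays. One array apart from the others is argued against, since leaving out each in turn left at least 0.59 of each list's median change relative to all genes (lowest for the stress list, without control 2). Background treatment stays open as a candidate explanation of part of the size. The bound set beforehand for between-array scaling was a drop under 0.5 in any of 3 settings. Without background correction both lists fell under it, the sterol list to 0.448 and the stress list to 0.466. That setting kept the quantile normalization, so its drop cannot decide about scaling. It also shrank the 142 changed genes, to 0.679 of their median size, so some shrinkage was not specific to the lists. Median centring and the authors' values did change the scaling. There the lists kept 1.01 and 0.907, and 1.05 and 1.09, which argues against the quantile normalization as the source of the rise relative to all genes. A constant factor per array cancels in these values, so they do not test one. Camera called both lists in all 3 settings at the preset correlation, while with an estimated correlation neither passed (adjusted p = 0.336 and 0.719). Of the 3 splits, 1 gave a sterol median as far from 0 (0.42 against 0.01 for the highest other), too few for a share under 0.05.

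Lower Aldh3a1 in mutants was weighed against less cornea carried over with the lenses, since this gene is abundant in both tissues. Of 6 abundant cornea transcripts (Krt12, Krt5, Krt14, Krt15, Kera and Lum), 0 were detected on both control arrays, and Krt15 reached detection on 1 of them. Aldh3a1 itself had background-subtracted signals of 2641 and 1387 there, which argues against cornea as its source. A change within the lens, with genotype as the difference the design names, remains a hypothesis. Nothing here tests it apart from the explanations left open above. The labels give cataract for the mutants only, so effects of genotype and of cataract cannot be told apart for any change reported here.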
